A study of Caenorhabditis elegans with 2 samples.

How the data were processed

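The series holds 2 chromatin immunoprecipitation sequencing (ChIP-seq) samples of 1 group, labelled as biological replicates 1 and 2. Each came from whole Caenorhabditis elegans at the L4 larval stage, 52.5 hours old per the labels, that carried a transgene for ZIP-11 fused to GFP. Chromatin was sonicated and precipitated with an antibody against GFP, per the labels. There was no second condition, so no comparison between groups was made. Each comparison set bound regions against other regions of the same lists, against placed positions, or against the other sample.

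The authors deposited 4 thresholded peak lists and 4 ranked peak lists on assembly ce11, which has the same sequence as WBcel235. A thresholded and a ranked list belonged to each sample, and the series added a thresholded list and a conservative list with their ranked lists, made from both samples together. The deposited notes on the files name 1 control alignment file and, for the thresholded lists, 1 further file that they do not describe. The aligner, the peak caller and their versions are not given in the sources used here. The authors' signal value of each peak came from their peak caller and measures ChIP over control on a scale that differs between lists. It was therefore used to describe, rank or filter peaks within a list. Between the samples it was only correlated or shown side by side, and no difference was tested. The authors' ranked lists also give −log10 of the global irreproducible discovery rate (IDR), a measure of how consistently a peak ranks in a pair of inputs. All peaks of the thresholded lists had a global IDR under 0.01, which was tested on the lists. A deposited score column, named by its format as a significance value, held values below 0 and entered no test. The 6 columns that give the inputs' signal in ranked lists other than the comparison of the 2 samples were not used. No list gives read counts, so the sequencing depth of each sample is unknown here, and intervals cover counting error over regions only.

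Overlapping peaks of a list were joined into regions, and the summit of the peak with the highest signal value was kept. Annotation came from Ensembl release 115, with tRNA isotypes and mitochondrial gene names from the RefSeq annotation of the same assembly. Mitochondrial names were matched at a reciprocal overlap of at least 80%. A promoter ran from 500 bp upstream to 100 bp downstream of an annotated transcription start site (TSS). Classes were given in the order promoter, 5′ UTR, coding exon, 3′ UTR, intron, other exon and intergenic. A short noncoding gene, of the tRNA, snoRNA, snRNA, SL RNA, rRNA or miRNA type, counted as near when its TSS lay within 250 bp of the summit. Pseudogenes and other noncoding genes, such as those for ribonuclease P and signal recognition particle RNAs and piRNAs, were not among these 6 types. Regions at them stayed in the set without short noncoding genes. A gene counted as bound when its TSS was the nearest to a summit and within 1000 bp of it.

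Other ranked regions were the regions of the pooled ranked list outside the thresholded list. Shares were compared with them by Fisher's exact test, two-sided, and have 95% Wilson intervals. Promoter shares and classes were also set against 10000 uniform placements within chromosomes, and chromosome shares against length with an exact binomial test. The overlap of the samples' lists was set against 10000 draws from the ranked list (one-sided permutation test). Gene lists held protein-coding genes only and were tested against genes of all types with a ranked region. Motifs within 50 bp of a summit were compared with flanks from 250 to 350 bp (exact McNemar test). They were also compared with 5 other ranked regions per region, matched on promoter class and on GC content in bins of 5 percentage points. All 6-, 7- and 8-mers joined with their reverse complements were searched in the same windows (Fisher's exact test, one-sided). Motif presence and signal rank were compared with 100000 resamples. Adjusted p-values are Benjamini-Hochberg values within each family, with a threshold of 0.05.

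Tests, 34 gene lists, 14 motifs and the rule for named genes were fixed before the data were examined. Of the list symbols, 6 had no match in the annotation. The rule named zip-11 and unc-119, the genes of the 20 regions of highest signal value that had a gene within 1000 bp, and up to 4 bound members of each list. Genes named outside this rule are said to have been chosen after their values were seen. The alternatives chosen at that point were the conservative list, the upper 50% of the thresholded list by signal, each sample's own list, and other joining, overlap, promoter, assignment and motif windows. Others were added after seeing the data and are named in the closing section. Sets at other global IDR levels were cut from the pooled ranked list, not from the thresholded list. Uniqueness of sequence was measured as the share of 31-mers within 140 bp of a summit that occur once in the genome, both strands joined.

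The tests over classes, gene types, chromosomes, gene lists, motifs, k-mers and list overlap were tested on simulated data. Of 100 sets of 349 regions drawn at random, 5 gave a call among annotation classes, 2 among noncoding gene types and 4 among chromosomes. Of 100 random sets of 290 bound genes, 4 gave a call among gene lists. All 24 gene lists of 20 or more genes were called when about 20% of their members were planted as bound. All 4 k-mers of a word planted in 69 of 349 windows were called, and 0 k-mers and 0 motifs were called with nothing planted. Smaller lists and weaker planted shares were not tried. None of 20 pairs of random lists passed the overlap test. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.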

Results

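Binding of ZIP-11, a transcription factor of the basic leucine zipper (bZIP) family, was measured by ChIP-seq in whole L4 larvae of C. elegans with a GFP-tagged transgene. The 2 samples were biological replicates per the labels and formed the only group. The values are the authors' peak positions and signal values. No read counts were in the lists, so the depth of each sample is unknown. Positions are on WBcel235, counted from 1.

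The pooled thresholded list held 364 peaks, which formed 349 regions with a median width of 280 bp. The conservative list formed 315 regions, and the samples' own lists formed 150 regions in replicate 1 and 102 in replicate 2. The strongest regions of the pooled thresholded list lay on mitochondrial DNA, beside snoRNA genes and at a few protein-coding loci. These loci included the HSP70-related genes F44E5.4 and F44E5.5 and the ribosomal protein gene rpl-3. Regions near nuclear tRNA genes were numerous, but the strongest of them ranked 30 of 349 by signal value. Of the 349 regions, 59 (16.9%) were in both samples' own lists and 179 (51.3%) were in neither, whereas 265 (75.9%) overlapped the conservative list.

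The samples' own lists shared regions at mitochondrial DNA, at snoRNA genes such as C51F7.4 and T03F7.8, and at tRNA genes such as M02F4.t1 and T03G6.t1, examples chosen after their values were seen. Of the 150 regions of replicate 1, 59 (39.3%, 95% interval 31.9 to 47.3) overlapped a region of replicate 2. Of the 102 regions of replicate 2, 59 (57.8%, 48.2 to 67.0) overlapped a region of replicate 1. Draws from the ranked lists gave means of 0.208% and 0.299%, and draws from the 5000 ranked regions of highest signal gave 1.87% and 2.52%. The permutation p was 0.0001 in both directions and with both sets of draws, the smallest these draws can give. The signal values of the samples had a Pearson r of 0.652 and a Spearman rho of 0.182 over 111931 ranked peaks. These are correlations across peaks of 1 experiment, and peaks are not independent replicates. At the thresholded regions with a value in both samples, r of the log2 values was 0.77 over 341 regions and 0.34 over the 323 nuclear ones, where rho was 0.157. The higher correlation thus rested on the mitochondrial regions.

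**Figure D1:**
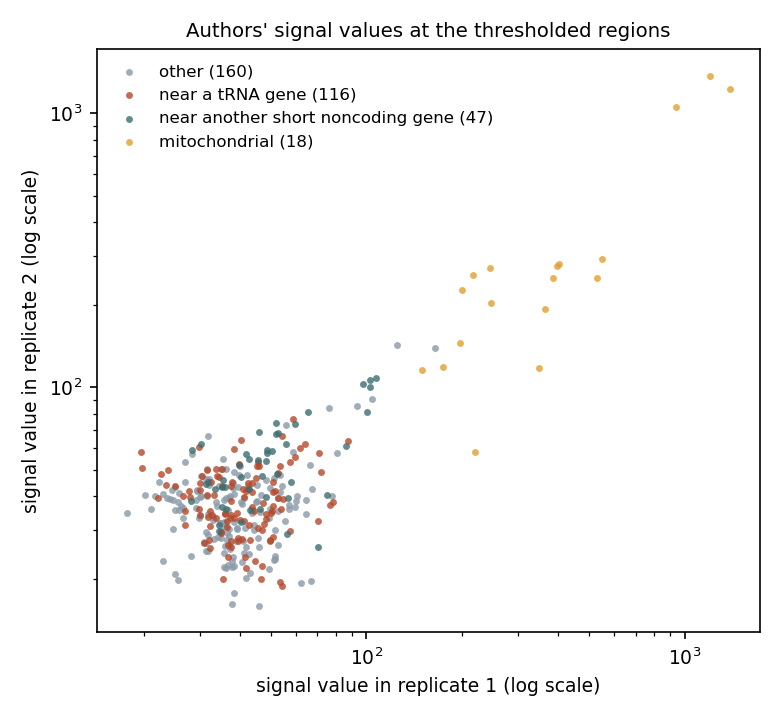
The authors' signal value in replicate 1 (x axis, log scale) against that in replicate 2 (y axis, log scale) at the 341 thresholded regions with a value in both; each point is a region, coloured by the kind of locus. Mitochondrial regions spread along the upper right, reaching 1381 in replicate 1 and 1369 in replicate 2, and most nuclear regions form a round cloud.

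The design asks where in the genome ZIP-11 was found. Summits were concentrated at promoters: 249 of 349 (71.3%, 66.4 to 75.8) lay in a promoter of any gene, against 22.8% of other ranked regions and 24.4% ± 2.2 (SD over placements) of uniformly placed positions. Promoters of protein-coding genes held 25.5% of summits (21.2 to 30.3), against 14.6% of other ranked regions. Coding exons held 5.73% against 25.4%, introns 6.88% against 25.9%, intergenic sequence 43 summits of 349 against 20.3%, and 3′ UTRs 0.287% against 2.60%. Fisher's exact test gave p = 4.1e-82 for promoters of any gene and p = 1.2e-07 for protein-coding promoters. By the same exact test the adjusted p was 2.0e-21 for coding exons, 2.0e-19 for introns, 1.8e-04 for intergenic sequence and 0.00278 for 3′ UTRs, while 5′ UTRs (adjusted p = 0.187) and other exons (adjusted p = 0.168) did not pass. In the list of replicate 2 alone, protein-coding promoters held 22.5% of summits against 15.2% of other ranked regions (p = 0.0514, Fisher's exact test). Among the 164 regions left without mitochondrial DNA and without regions near tRNA, snoRNA, snRNA, SL RNA, rRNA or miRNA genes, 43.9% lay in a promoter of any gene (36.5 to 51.6) and 31.1% in a protein-coding promoter (24.5 to 38.6). The intergenic share of these regions was 25%, above the 20.3% of other ranked regions (adjusted p = 0.169, Fisher's exact test). Their coding exon share was 9.15% and their intron share 14.02%, and at a global IDR under 0.05 these shares were 18.7% and 11.7%, all still below those of other ranked regions.

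Genes for tRNAs stood beside 125 of the 349 regions (35.8%, 31.0 to 41.0), against 0.393% of other ranked regions, a 91.0-fold difference. Of these regions 6 were mitochondrial, and the rest lay at nuclear tRNA genes, which are transcribed by RNA polymerase III. Genes for snoRNAs, which guide the modification of other RNAs, stood beside 41 regions (11.7%, 8.78 to 15.6), against 0.203%, a 57.7-fold difference. Genes for spliced leader (SL) RNAs, which supply the trans-spliced 5′ end of many worm mRNAs, stood beside 3 regions, including those at sls-2.1 and sls-2.9, named after their values were seen. In all, 172 regions (49.3%, 44.1 to 54.5) lay near a gene of the 6 short noncoding types tested, against 0.836%. The median signal value was 77.2 over nuclear regions near tRNA genes, 97.9 over those near snoRNA genes and 70.1 over the 164 remaining regions.

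Fisher's exact test gave an adjusted p of 1.8e-195 for tRNA genes, 1.8e-55 for snoRNA genes and 6.0e-05 for SL RNA genes. Genes for snRNAs (2 regions, adjusted p = 0.0326) and rRNAs (1 region, adjusted p = 0.0326) passed by exact test on few regions, and miRNA genes (2 regions, adjusted p = 0.0984) did not. The rRNA region was mitochondrial. The single-sample lists had tRNA shares of 36% against 0.813% of other ranked regions in replicate 1 and 33.3% against 0.883% in replicate 2, so the fold was lower there. The tRNA share was 20.4% at a global IDR under 0.05 and 22.99% under 0.001. The snoRNA share was 16% in the list of replicate 1 and 24.5% in that of replicate 2. It was 20% in the upper 50% of the pooled list by signal and 4.58% at a global IDR under 0.05. Sequence at many tRNA genes occurs in several copies, and 49 of the nuclear regions near tRNA genes (41.2%, 32.7 to 50.2) had a summit 31-mer found once in the genome, against 94.6% of other ranked regions.

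**Figure D2:**
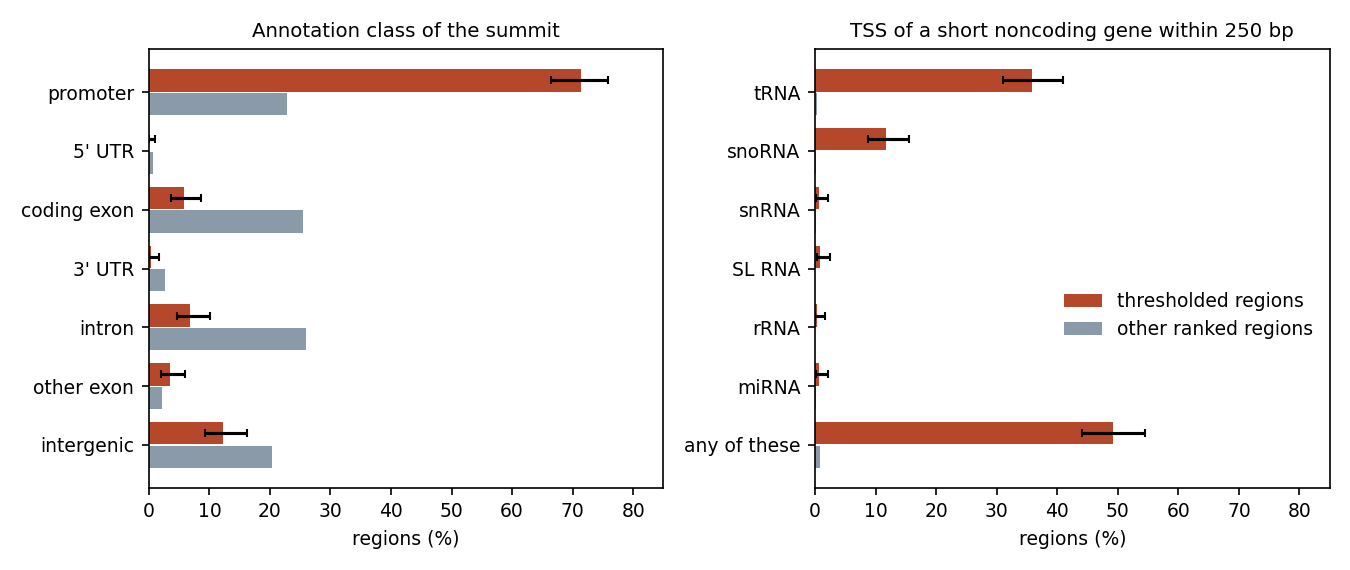
Percent of regions (x axis) by annotation class of the summit (left) and with the TSS of a short noncoding gene within 250 bp (right). Red bars are the 349 thresholded regions with 95% Wilson intervals, and grey bars are other ranked regions; promoters (71.3% against 22.8%) and tRNA genes (35.8% against 0.393%) stand apart.

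Mitochondrial DNA carried the highest signal values of the list. It makes up 0.0137% of the genome's length, a share that takes no account of copy number. It held 19 of the 349 regions (5.44%, 3.51 to 8.35), with a median signal value of 593.8. The highest lay within CYTB, which encodes cytochrome b (4619 to 4883, signal value 2628), followed by a region beside the mitochondrial tRNA-Ala gene (13056 to 13343, 2521) and one within ND5, a subunit of respiratory complex I (12337 to 12595, 2117). Others among the 20 named regions had COX1, COX3, ATP6, ND2, ND3 or the tRNA genes for His, Thr, Lys, Cys, Tyr and Ala as the nearest gene, with values from 254.2 at COX3 to 855 within COX1. Fisher's exact test against other ranked regions, of which 1 was mitochondrial, gave an adjusted p of 3.0e-45. Of 20 ranked mitochondrial regions, 19 were thresholded.

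**Figure D3:**
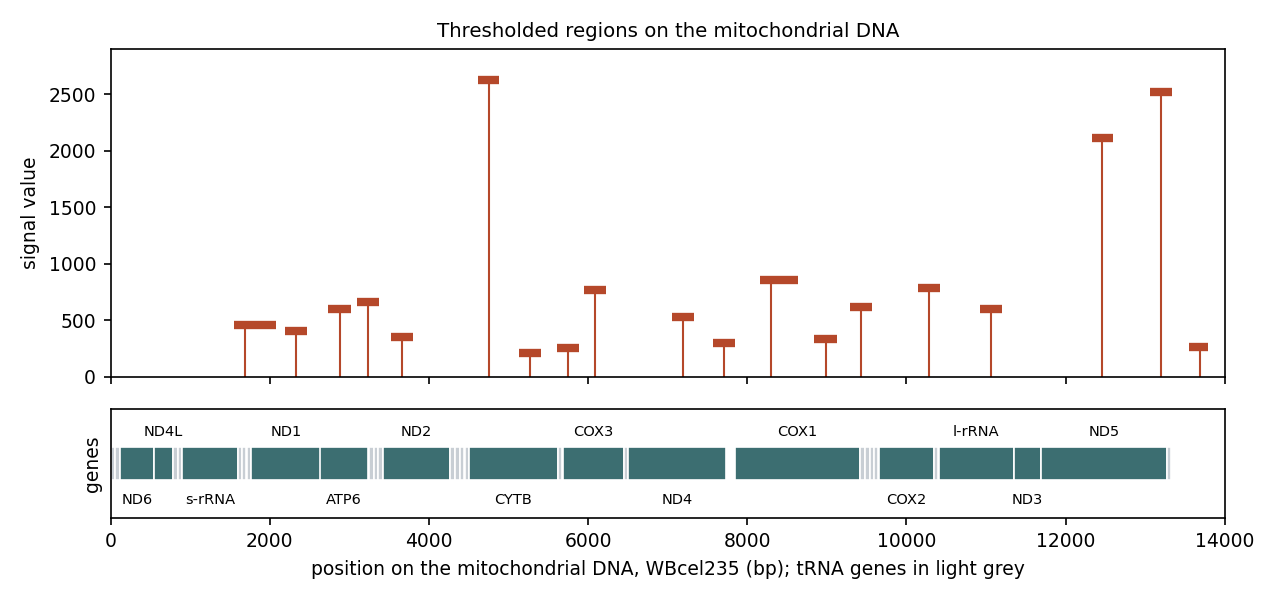
Authors' signal value (y axis) of the 19 thresholded regions along the mitochondrial DNA (x axis, bp), with the width of each region as a bar and its summit as a line, above the annotated genes. The 3 highest, at 2628, 2521 and 2117, lie in CYTB, beside tRNA-Ala and within ND5.

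Among nuclear chromosomes, X held 90 of the 349 regions (25.8%, 21.5 to 30.6) against 18.8% of other ranked regions, and V held 50 (14.3%, 11.0 to 18.4) against 21.2%. The adjusted p by Fisher's exact test was 0.00361 for X and 0.00361 for V. I, II, III and IV did not pass, with adjusted p from 0.14 for IV to 0.693 for II and III. Against chromosome length, IV was also lower (44 of 349 regions against 17.4% of the length, exact binomial test, adjusted p = 0.0286). In the samples' own lists the X share was 21.3% in replicate 1 (adjusted p = 0.507) and 26.5% in replicate 2 (adjusted p = 0.0893), both by Fisher's exact test. At a global IDR under 0.05, with 1005 regions, the X share was 20.8% (adjusted p = 0.177, Fisher's exact test). The V share was 16.7% in both lists (adjusted p = 0.466 and 0.386, Fisher's exact test), and in the upper 50% of the pooled list by signal its adjusted p was 0.168. Among the 164 regions left without mitochondrial DNA and the short noncoding types, the X share was 17.1%, below that of other ranked regions, and the V share was 18.3% (adjusted p = 0.805, Fisher's exact test).

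The strongest nuclear region of the thresholded list lay at the noncoding RNA gene F44E7.13 (V, 5780788 to 5780954, signal value 306.3). It was followed by the shared promoter of F44E5.4 and F44E5.5, which encode HSP70-family chaperones (II, 11759329 to 11759608, 274.7). Both regions were in both samples' own lists, and the samples' signal values were 164.2 and 139.4 at F44E7.13 and 125.1 and 142.7 at F44E5.4. Next, and named after their values were seen, came the snoRNA genes C51F7.4 (V, 12303493 to 12303772, 221.3), T03F7.8 (V, 11314174 to 11314244, 211.2) and W03C9.9 (II, 11960803 to 11960872, 204.4). The promoter of rpl-3, a protein of the large ribosomal subunit, had a value of 196.7 (III, 3867422 to 3867701). Among nuclear regions of that list with a summit within 250 bp of a tRNA TSS, the strongest had a value of 153.8. Also named after its value was seen, it lay between M02F4.t1 and M02F4.t2 (X, 3036007 to 3036286), genes for tRNA-Gly and tRNA-Glu.

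Of 290 bound genes, 85 were protein-coding. Ribosomal protein genes were the list bound more often than other genes, with 5 of 66 (7.58%) against 1.01%. The other genes were of all types, tRNA and snoRNA genes included, whereas the lists held protein-coding genes only. They were rpl-3, rpl-35 (signal value 114.6), rpl-15 (87.5), rpl-27 (76.4) and, named after its value was seen, rps-6 (61.4). The rps-6 summit lay 768 bp downstream of its TSS, in intergenic sequence past the end of the gene. With all 5 genes the adjusted p was 0.0204 by Fisher's exact test over the 34 lists. The test was not repeated without rps-6. In the upper 50% of the list by signal the share was 4.55% against 0.534% (adjusted p = 0.191, Fisher's exact test). It was 5.26% against 0.677% in the list of replicate 1 (adjusted p = 0.244) and 1.92% against 0.456% in that of replicate 2 (adjusted p = 1), by the same exact test on fewer regions. When every gene with a TSS within 1000 bp was counted, 11 of 81 ribosomal protein genes were bound, including rpl-20 (91.3) and rps-26 (88.1), with an adjusted p of 7.4e-06 by Fisher's exact test. Among these, the summits of rps-6 and, named after their values were seen, rpl-31 and rps-25 lay past the end of the gene. The rps-26 region also had a snoRNA TSS within 250 bp of its summit.

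Heat shock and cytosolic chaperone genes had 1 bound member of 18 (F44E5.4) under the nearest-gene rule (adjusted p = 1 by Fisher's exact test). Under the rule of every gene they had 5 of 24: F44E5.4, F44E5.5, hsp-90 (68.0), hsp-1 (65.8) and, named after its value was seen, dnj-13 (64.6). The adjusted p by Fisher's exact test was then 9.8e-04, although F44E5.4 and F44E5.5 share a region. The endoplasmic reticulum chaperone gene hsp-3 (63.2) was bound among 21 genes of the unfolded protein response, nhr-141 (82.9) among 243 nuclear hormone receptor genes, ins-39 (90.4) among 122 neuropeptide and insulin-like genes, and cpz-1 (69.96) among 55 autophagy and lysosome genes. None of these 4 lists passed, with an adjusted p of 1 for each by Fisher's exact test. In the other 28 lists no gene was bound under the nearest-gene rule. These included 27 bZIP factor genes, 99 innate immune effector genes, 215 C-type lectin genes, 199 detoxification genes, 28 translation factor genes, 28 aminoacyl-tRNA synthetase genes and the markers of intestine, muscle, hypodermis, neurons, pharynx and germline. Genes outside each of these lists were bound at 1.03% to 1.04%, so a count of 0 does not show that a list was avoided. These rates cover genes of all types, and most bound genes were not protein-coding. The lowest unadjusted p of the 28 lists was 0.179, for C-type lectin genes (Fisher's exact test). Under the rule of every gene, 3 C-type lectin genes, 3 detoxification genes and 1 gene each of the collagen, mitochondrial unfolded protein response, oxidative phosphorylation and gonad sheath and vulva lists had a region (clec-99, clec-196 and clec-126; cyp-43A1, gst-27 and dhs-8; col-85, hsp-60, cox-6A and egl-17). None of these lists passed, with an adjusted p of 1 for each by Fisher's exact test. The regions of clec-99, clec-126, cyp-43A1, col-85 and egl-17 also lay near a tRNA gene. That of gst-27 lay near a snoRNA gene and that of cox-6A near an snRNA gene. The oxidative phosphorylation list left out genes on mitochondrial DNA, such as CYTB, ND5 and COX1, which had regions.

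No motif recognised by bZIP factors passed a test for a higher share at summits. The CRE core TGACGT lay within 50 bp of 6 of 349 summits (1.72%, 0.79 to 3.70), against 1.86% of flanks and 4.13% of matched ranked regions. With windows of 100 bp it was less frequent than in matched regions, at 3.44% against 7.79% (adjusted p = 0.0127, Fisher's exact test). Among the 164 remaining regions, in windows of 50 bp, it stood at 3.05% against 3.05% of matched regions (adjusted p = 1, Fisher's exact test). The AP-1 site stood at 3 summits, the ATF4-type site at 6, and the CRE or PAR site TKACGTMA at 0 (interval up to 1.09%). The splice acceptor TTTNCAG was less frequent at summits, at 4.87% against 16.9% of flanks and 10.8% of matched regions. Its adjusted p was 5.3e-05 by the exact McNemar test and 0.00502 by Fisher's exact test, and the other 13 motifs did not pass either test. Against matched regions it stayed lower but lost its call in the conservative list (6.35% against 10.3%, adjusted p = 0.169) and in the upper 50% of the list by signal (5.71% against 9.83%, adjusted p = 0.747), by Fisher's exact test. The same held in replicate 1 (6.67% against 12.33%, adjusted p = 0.226), in replicate 2 (5.88% against 11.4%, adjusted p = 0.781) and among the 164 remaining regions (5.49% against 11.7%, adjusted p = 0.126), by the same exact test on fewer regions. Against flanks the call was lost in the upper 50% (5.71% against 17.4%, adjusted p = 0.127) and in replicate 1 (6.67% against 13.7%, adjusted p = 0.802) by the exact McNemar test. With windows of 100 bp the GAGA repeat was found at 27.8% of summits against 11.6% of flanks (adjusted p = 1.5e-05, exact McNemar test) and 18.2% of matched regions. In the main windows it stood at 44 of 349 summits against 6.73% of flanks (adjusted p = 0.106, exact McNemar test) and 11.2% of matched regions (adjusted p = 0.752, Fisher's exact test). No motif was related to signal rank after adjustment. The lowest unadjusted permutation p of the 12 motifs tested was 0.0495, for the TATA-like motif.

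The search over 43168 k-mers called 361 that were enriched at summits, led by words of tRNA genes. GTTCGA, part of the B box, the internal promoter element of tRNA genes, lay in 24.6% of windows against 5.04% of matched windows, and GGTTCGA in 18.3% against 2.58%. ACCACT was found in 26.1% against 5.50%, and its longer form AGTGGTTA, on the opposite strand, in 10.6% against 0.802%. The adjusted p was 8.8e-22 for GTTCGA, 1.4e-20 for GGTTCGA and 1.9e-22 for ACCACT by Fisher's exact test. Among the 164 regions left without mitochondrial DNA and the 6 short noncoding types, 23 k-mers were called, led by CACTCGGC (6.71% against 0.122%). This word was also called over all regions (5.16% against 0.573%). Others, such as AACCACTC (6.10% against 0.366%), contain ACCACT. These 164 regions may therefore still hold sequence like that of tRNA genes. The samples' own lists gave between 1 and 4 k-mers.

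The transgene carries zip-11 and unc-119, a gene used to rescue the movement defect of the host strain, and extra copies can raise signal at both genes. No thresholded region lay within 20000 bp of zip-11 (IV, 3311276 to 3313189) or of unc-119 (III, 10902641 to 10908935) in the pooled, conservative or single-sample lists. Within 1000 bp of zip-11 there was no ranked region either. Within 1000 bp of unc-119 there were 10 pooled ranked regions, and the highest had a signal value of 29.1, above 83.4% of ranked peaks. In the samples' own ranked lists the highest there was above 79.4% of peaks in replicate 1 (19.3) and 25.8% in replicate 2 (9.39).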

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

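The tests of promoter location and of the cover of mitochondrial DNA were chosen only after the results they concern were seen. The design has 1 group and gives no biological explanation for these patterns, so no biological explanation was tested in this part. A hypothesis on bound snoRNA genes has its test among the other observations.

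Some ranked regions that passed the global IDR threshold of 0.01 were missing from the thresholded lists. No comparison tested them on their own. Being outside the thresholded list, they could be among the other ranked regions. There were 32 in the pooled list, 28 in the conservative list, 30 in the list of replicate 1 and 11 in that of replicate 2. The pooled ones had a median signal value of 108, and the highest (X, 15810959 to 15811050) reached 403.1. In these 32 regions a median of 7.97% of 31-mers occurred once in the genome, at most 39.8%, against a median of 97.6% in the listed regions, and joining the missing regions of the 4 lists gave 42, of which 0 overlapped a region of any thresholded list. Both values are in line with removal of fixed positions rich in repeated sequence, which may be what the further file in the authors' notes holds, although 33 listed regions also had under 50% of their 31-mers unique.

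Regions near tRNA and snoRNA genes made up much of the list. A location in promoters in general is argued against for tRNA genes, since among nuclear promoter regions the tRNA share was 30.6 times that of other ranked regions (25.99 to 36.05). The tRNA and promoter shares, known before the bounds of this test were set, largely fixed this fold. It is therefore not separate evidence for the difference at tRNA genes. Reads shared between near-identical copies are argued against for snoRNA genes, where 100% of the 41 summits had a 31-mer found once. For tRNA genes the share was 41.2% (32.7 to 50.2), between the bounds set for and against, and a median of 78.5% of the 31-mers around these summits occurred once, so shared reads cannot be told apart from binding at each copy. Binding by ZIP-11 and a general pull-down of chromatin at highly transcribed short genes both stay open, because no precipitation from worms without the tag was analysed here.

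The regions on mitochondrial DNA had the highest signal values. Nuclear copies of mitochondrial sequence are argued against, since 0.16% of mitochondrial 31-mers also occur on a nuclear chromosome. Ranked regions covered 45.0% of the molecule and thresholded regions lay in 9 of its 10 equal parts. The bound set against a signal raised along the whole molecule was a cover under 50%, which this value met, but the bound was set aside after the value was seen, because 99.99% of ranked peaks were 280 bp wide and peaks of a fixed width leave gaps however even the signal is. A signal raised along the whole molecule and binding at separate sites therefore cannot be told apart from peak positions alone. A pull-down of mitochondrial DNA without binding by ZIP-11 also stays open, because no precipitation from worms without the tag was analysed here.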

How the results depend on the processing

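The looser and stricter global IDR levels, the nuclear regions alone, the regions without mitochondrial DNA and short noncoding genes, the protein-coding assignment and background, and all alternatives for the transgene genes were chosen only after the results were seen. Promoter share, noncoding gene share, overlap of the samples' lists, the absence of motifs related to signal and the absence of regions at zip-11 and unc-119 kept their direction and their side of the threshold under every alternative run. Promoter share ranged from 25.5% to 79.4% and noncoding gene share from 26.5% to 60%. Of 98 alternative values of the results set in the design 64 kept their call or stayed within 1.5 times and 34 moved. Of 150 for single classes, chromosomes, lists and motifs, 22 lost and 5 gained significance, 4 reversed and the rest kept their call. Cut from the pooled ranked list, an IDR under 0.05 gave 1005 regions and an IDR under 0.001 gave 87. These sets can also hold the regions missing from the thresholded list, which were not counted in them. Pearson r between the samples was 0.935 over thresholded regions (Spearman rho 0.352) and 0.917 over the 5000 ranked first (rho -0.078). Under an IDR of 0.001 there were 3 annotation classes, 1 chromosome, 1 k-mer, 0 gene lists and 0 motifs by either test. Under 0.05 there were 3 motifs against flanks and 2 against other regions. Without mitochondrial regions and regions near short noncoding genes there were 0 chromosomes, 23 k-mers and 0 motifs against other regions. In the upper 50% of the list by signal there were 181 k-mers, 0 gene lists and 0 motifs by either test. The conservative list gave 2 motifs against flanks and 0 against other regions, and windows of 100 bp gave 2 and 3. Counting every gene within 1000 bp, or the nearest protein-coding TSS, gave 2 gene lists. With a single sample's list there was 1 chromosome from either sample, 1 to 4 k-mers, 0 gene lists from either, 0 to 1 motifs against flanks and 0 against other regions. The X share turned below that of other ranked regions at an IDR under 0.001 (18.4%) and without mitochondrial regions and regions near short noncoding genes (17.1%). The intergenic share turned above it in the same settings (25.3% and 25%). The stricter lists and single-sample lists hold fewer regions; otherwise the cause was not tested. The noncoding gene share has no value without the regions near such genes. No paired analysis was possible because there was 1 group. Read depth is unknown here, so its effect on list length could not be measured.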

Other observations

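The genes and groups in this part, and the test of the X share without short noncoding genes, were chosen only after the results were seen. Small RNAs other than tRNAs that RNA polymerase III makes were also among the bound loci, with a region at 5 of 8 such genes looked up. The 8 did not include genes annotated as rRNA or snRNA, which had 0 and 2 of the 330 nuclear regions near them. The gene for the RNA of ribonuclease P, rpr-1 (I, 13463955 to 13464207), had a signal value of 142.5, and mrpr-1, which encodes the RNA of ribonuclease MRP, had 85.3. Of the signal recognition particle RNA genes, srpr-2.1 had 86.4, srpr-2.2 81.7 and srpr-1.1 74.2, while srpr-1.2, srpr-3 and the Y RNA gene yrn-1 had no region.

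Of 612 nuclear tRNA genes, 139 (22.7%, 19.6 to 26.2) had a thresholded summit within 250 bp. Genes for tRNA-Ala were bound most often, 16 of 34 (47.1%, 31.5 to 63.3; adjusted p = 0.0156 over 21 isotypes, Fisher's exact test). Genes for tRNA-Gln were bound in 0 of 27 (up to 12.5%; adjusted p = 0.0156, Fisher's exact test). Genes for tRNA-Gly (20 of 55, 36.4%) and tRNA-Arg (3 of 44, 6.82%) had adjusted p of 0.0902 and 0.0555 by Fisher's exact test. These tests, and those of tRNA genes on X and of snoRNA genes, treat genes as independent, whereas a region can count several neighbouring genes, such as F15G9.t1 and F15G9.t2, both for tRNA-Ala. Reads shared between tRNA gene copies were also left open.

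A hypothesis for the higher X share is that it follows tRNA genes, of which 45.1% lie on X. Without mitochondrial regions and regions near short noncoding genes the X share was 17.1% (12.08 to 23.6; p = 0.618 by Fisher's exact test), against 18.8% of other ranked regions, which is consistent with it. Binding of tRNA genes on X may also be more frequent: 73 of 276 (26.4%) were bound on X and 66 of 336 (19.6%) on autosomes. The difference had p = 0.0524 by Fisher's exact test, so this remained open.

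A hypothesis for the snoRNA genes is that the bound ones carry a B box, the internal promoter element of tRNA genes. A match to the B box consensus lay between 100 bp upstream of the TSS and the gene end in 22 of the 42 bound genes (52.4%, 37.7 to 66.6) and in 25 of the 304 others (8.22%, 5.63 to 11.9). Fisher's exact test gave p = 4.8e-11. This is consistent with the bound snoRNA genes being a subset that RNA polymerase III may transcribe, which was not measured here. The other 20 bound genes had no match.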
